A study of Homo sapiens with 12 samples.

How the data were processed

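Gene expression was measured on 12 Affymetrix arrays from SKM1, an established human cell line derived from a myeloid leukaemia. The arrays fell into 4 groups of 3, by the labels: untreated cells (NT), cells given APR-246 (APR), cells given 5-azacytidine (AZA) and cells given both (APR-AZA). Each drug was used at its IC50, and RNA was taken at 18 h. Per the labels' protocols, 250 ng of total RNA was labelled for each array with a whole-transcript kit, which converts RNA to biotin-labelled, fragmented sense-strand DNA. The drug concentrations are not given in the sources used here.

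The values deposited by the authors are on the log2 scale, 1 value per gene and array. Per the submitters' processing notes they were made with RMA, which corrects background, sets the arrays to a common distribution by quantile normalization and summarises the probes of each gene, and Partek is named there too, with no version of either. The chip definition, genome build and annotation are not given in the sources used here, so no genomic position is printed. RMA pulls the arrays' distributions together, so a shift of most genes in one direction would be removed before these values were made, and low signals are compressed, so fold changes of dim genes are understated. Array medians lay between 4.69 and 4.78 on the log2 scale. Arrays have no counting depth, and the number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

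The table held 29413 rows, of which 28129 have 1 gene symbol in the platform annotation, 0 have several and 1284 have none. Rows without a symbol were left out of the comparisons, and for the 4 symbols on more than 1 row the row with the highest mean was kept, which left 28125 genes. No filter on signal was applied. The planned list of genes to be named held 1 gene that is not reported here. No array pair looked like a repeat deposit, since at most 0.0952% of values were identical between any pair of arrays.

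Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) in 1 model with a mean for each of the 4 groups and no covariate, so that all 12 arrays shared an estimate of the spread with 8 residual degrees of freedom. The comparisons were each treatment against NT, the combination against each single drug, APR against AZA, and non-additivity, the change with both drugs minus the sum of the changes with each. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. Fold changes are given with the moderated standard error on the log2 scale.

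A set of 35 gene lists with 939 entries, fixed before the data were examined, was tested with camera, which compares a list with all other genes, at its preset inter-gene correlation of 0.01. Of the entries, 852 were measured, 31 of them matched through an older symbol with a reference gene table of assembly GRCh38.p14 that was used for names alone. The same lists were run with camera's estimated correlation and with fry, which tests whether the genes of a list move on balance one way and makes no comparison with other genes. Members called are counted over all genes tested and also adjusted over the list alone. A gene can sit on several lists, as SLC7A11 and PMAIP1 do.

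The genes named were chosen by a rule fixed in advance. For each treatment against NT it took the 10 largest increases and 10 largest decreases among called genes whose 3 treated values lay on one side of the 3 NT values. For the other comparisons it took 5 in each direction. For each list described it took the 4 called members with the largest changes, or, where fewer were called, those and the members with the largest changes up to 2. CDKN1A, MDM2, BBC3, PMAIP1, FLT3, HMOX1, SLC7A11, DNMT1 and MYC were to be given in every comparison with NT. Genes named outside this rule are marked as chosen after their values were seen.

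Correlations between fold changes that share the NT arrays were set beside 100 simulations of unchanged groups sharing 3 controls. The fit was tested on simulated data for APR-AZA against AZA with 28125 genes, 200 of them changed. It called 97.0% of the 2-fold changes, 100% of the 4-fold changes and 64.2% of the 1.41-fold changes, with 11 false calls. In a simulation of APR against NT in which the NRF2 targets were raised by 0.2 on the log2 scale, camera called that list and 0 of the other 34. The simulated genes varied independently of each other, so this does not test false calls of lists whose genes vary together.

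Alternatives fixed before the data were examined were a filter on the dimmest 30% of genes, a repeated quantile normalization, median centring, a trended and robust variance, a linear model without moderation, a fit of the compared groups alone, the replicate number as a block, array weights, other treatments of repeated symbols, stricter thresholds and leaving out each array in turn. A pseudocount did not apply to log2 values. The effect of APR averaged over both AZA states was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.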

Results

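The effect of APR-246 and 5-azacytidine, alone and together, on gene expression was measured in SKM1 cells at 18 h. 5-Azacytidine (AZA) is a cytidine analogue that is built into RNA and DNA and traps DNA methyltransferases. APR-246 (APR) is a prodrug whose active product binds thiol groups of proteins and of glutathione. The 4 groups, untreated (NT), APR, AZA and APR-AZA, had 3 arrays each, and 28125 named genes were tested. The first principal component held 63.9% of the variance and separated the 6 arrays with AZA from the 6 without. Across all rows of the table, arrays of the same group correlated at 0.994 to 0.996. NT and APR arrays correlated at 0.994 to 0.996 with each other, and arrays with and without AZA at 0.978 to 0.984.

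**Figure D1:**
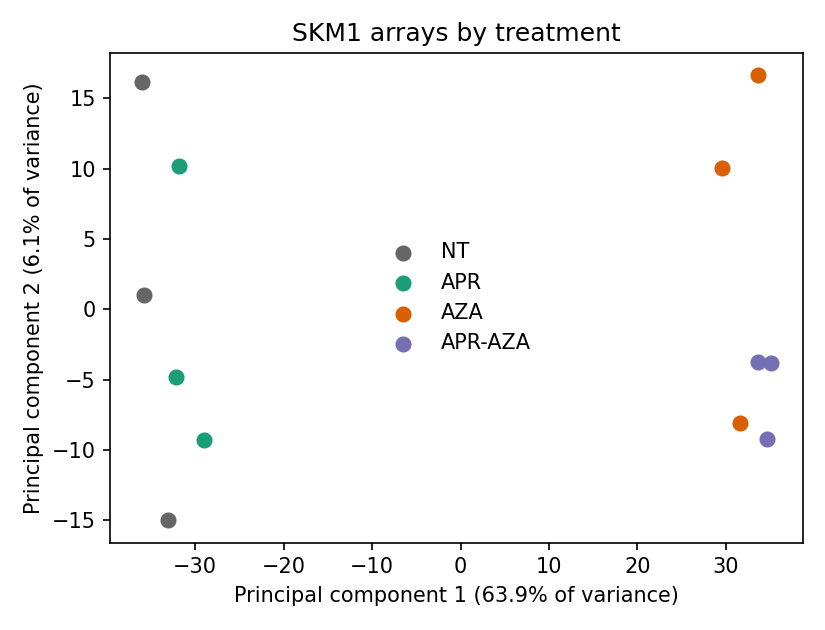
Each point is 1 array, placed by its first and second principal components over 28125 genes (arbitrary units), with colours for the 4 treatments of 3 arrays each. The arrays with AZA lie between 29.55 and 35.1 on the first axis and those without between -36.03 and -29.03.

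The first question was what APR alone changed against untreated cells. NQO1, a quinone reductase and a classical target of the oxidative stress factor NRF2, was 1.87-fold higher with APR, a log2 change of 0.91 ± 0.09 (SE, n = 3 per group). Its log2 signal was 7.89 ± 0.07 (SD, n = 3) in NT and 8.80 ± 0.17 (SD, n = 3) in APR, with all 3 APR arrays above all 3 NT arrays. NRF2 targets rose as a list, with a median log2 change of 0.17 over 25 measured members. Of these, 21 lay above 0, and HMOX1, also on this list, lay below it. Heat shock genes, which encode chaperones, rose by a median of 0.06 on the log2 scale over 26 members.

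NQO1 was the 1 gene of 28125 called (limma adjusted p = 0.0107). At an unadjusted p under 0.05 there were 1095 genes, where 1406 would be reached by chance. Among the NRF2 targets 1 member was called over all genes and 10 adjusted over the list alone. The list itself had a camera adjusted p of 7.19e-14, and adjusted p = 0.025 with an estimated correlation. OSGIN1, an oxidative stress-induced growth inhibitor, had a log2 value of 0.56 ± 0.12 (SE) that was not called (adjusted p = 0.959). For the heat shock list the adjusted p was 0.00106, and adjusted p = 0.0358 with an estimated correlation, with 0 members called by either count. The inducible HSP70 genes HSPA1B and HSPA1A stood at 0.30 ± 0.09 and 0.26 ± 0.10 (log2, SE), and the probes of this near-identical pair may read both.

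A further 5 lists were called with APR at camera's preset correlation and with neither the estimated correlation nor fry. Cholesterol synthesis and uptake had a median of -0.07 (adjusted p = 0.00269), and adjusted p = 0.0519 with an estimated correlation. Its members INSIG1, a brake on sterol synthesis, and DHCR7, the last enzyme of the pathway, stood at -0.37 ± 0.09 and -0.22 ± 0.12. Antigen presentation had a median of -0.05 (adjusted p = 0.0183), and adjusted p = 0.607 with an estimated correlation, with HLA-DPB1 at -0.34 ± 0.10 and HLA-DRB1 at -0.22 ± 0.11. Autophagy and lysosome had a median of 0.07 (adjusted p = 0.0241), and adjusted p = 0.495 with an estimated correlation, with TFE3 at 0.32 ± 0.12 and SQSTM1 at 0.23 ± 0.12. The unfolded protein response of the ER had a median of -0.06 (adjusted p = 0.0367), and adjusted p = 0.446 with an estimated correlation, with DERL3 at -0.31 ± 0.09 and MANF at -0.24 ± 0.10. MYC targets and ribosome biogenesis had a median of -0.03 (adjusted p = 0.0444), and adjusted p = 0.607 with an estimated correlation, with MYC at -0.24 ± 0.09 and NPM1 at -0.21 ± 0.12. In these 5 lists 0 members were called over all genes, and adjusted over the list alone 1 was, in the cholesterol list.

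Each of these 5 lists lost its call when some arrays were left out. The cholesterol list lost it without APR replicate 1 (adjusted p = 0.0858), NT replicate 1 (0.0505) or NT replicate 3 (0.0654), and antigen presentation without APR replicate 1 (0.596) or NT replicate 1 (0.542). Autophagy and lysosome genes lost it without APR replicate 2 (0.214), APR replicate 3 (0.125) or NT replicate 3 (0.273). Without APR replicates 1 and 2 and NT replicates 1 and 3, each left out alone, the ER list stood at 0.285, 0.06, 0.233 and 0.0712 and MYC targets at 0.254, 0.134, 0.45 and 0.0712. NRF2 targets and heat shock genes kept their calls in each of these runs.

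Other genes of interest were not called with APR alone. The proapoptotic PMAIP1 and BBC3 stood at 0.34 ± 0.10 and 0.28 ± 0.11 (log2, SE), the cystine transporter SLC7A11 at 0.31 ± 0.09 and the receptor kinase FLT3 at -0.38 ± 0.14. The cell cycle inhibitor CDKN1A stood at -0.10 ± 0.10, MDM2 at 0.00 ± 0.10, HMOX1, which degrades haem, at -0.18 ± 0.11, MYC at -0.24 ± 0.09 and the maintenance methyltransferase DNMT1 at -0.07 ± 0.07, each with an adjusted p of 1. The p53 targets had a median of 0.00 and were not called (camera adjusted p = 0.603, and 0 of 31 members called by either count). The call of NQO1 was lost without variance moderation (adjusted p = 0.202), with the compared groups alone (0.437), without NT replicate 2 (0.114) and without NT replicate 3 (0.116), over a range of 0.000785 to 0.437 across its alternatives. Of the 7 lists, 3 stayed called without APR replicate 1, NT replicate 1 or NT replicate 3, 4 without APR replicate 2, 6 without APR replicate 3 and all 7 without NT replicate 2. Leaving out APR replicate 3 or NT replicate 3 also called 1 list that was not among the 7.

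**Figure D2:**
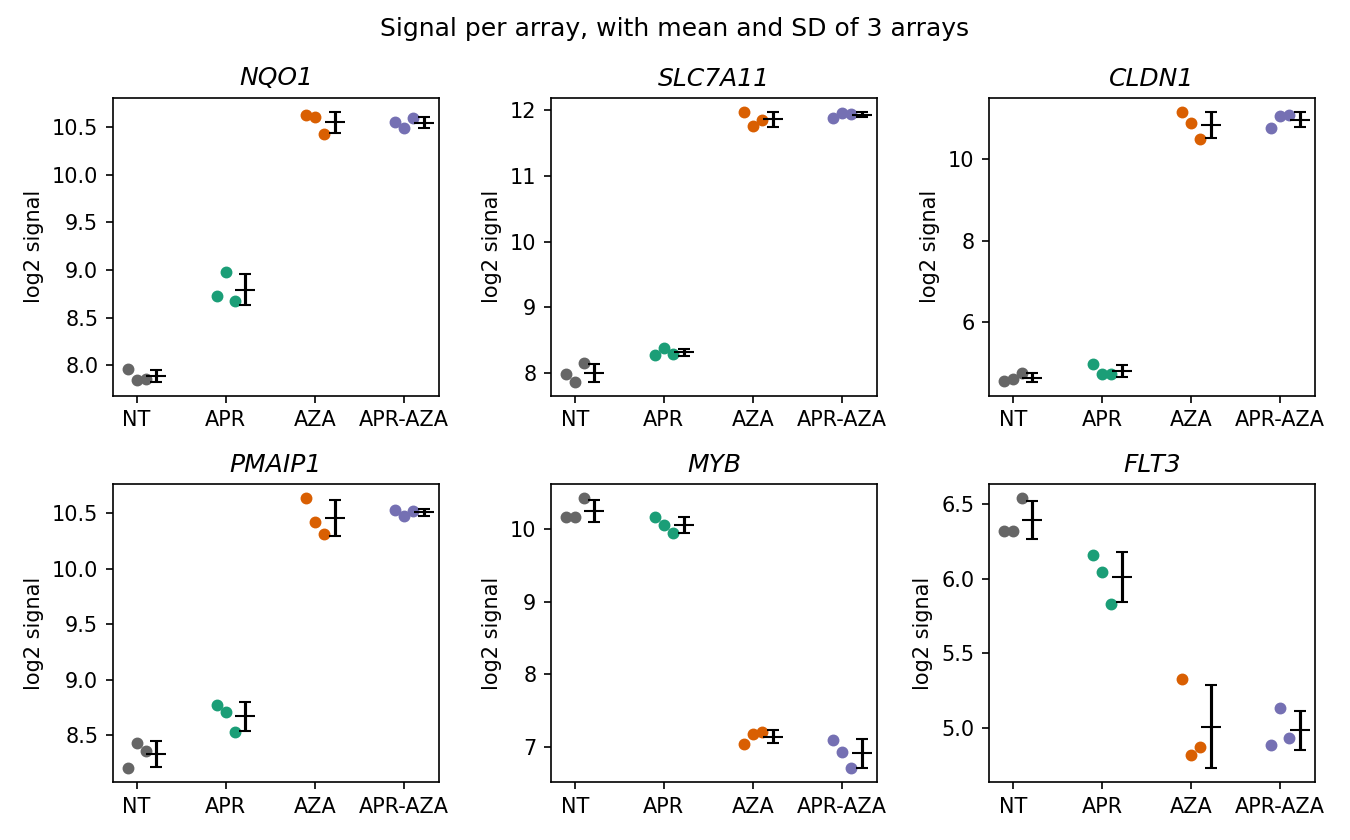
Each panel shows the log2 signal of 1 gene on every array by treatment, and the black bars give the mean and SD of 3 arrays; the vertical axes do not start at 0. NQO1 stands at a mean of 7.89 in NT, 8.80 in APR, 10.55 in AZA and 10.55 in APR-AZA, while MYB falls from 10.26 in NT to 7.14 in AZA.

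AZA alone changed 20.9% of the measured genes. CLDN1, a tight junction protein, was 73.3-fold higher, at 4.64 ± 0.11 (log2, SD, n = 3) in NT and 10.84 ± 0.32 in AZA. DDIT4, a stress-induced inhibitor of mTORC1, was 27.7-fold higher, and MYB, a transcription factor of blood progenitors, was 8.68-fold lower. Genes of the ATF4 and amino acid response rose in all 29 measured members, by a median of 1.40 on the log2 scale, and genes of ribosome biogenesis fell in 28 of 29, by a median of -0.72. With limma, 5878 genes were called, 2754 higher and 3124 lower, of which 502 were at least 2-fold higher and 406 at least 2-fold lower.

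The other 8 of the 10 largest increases were the antisense RNA BET1-AS1 (28.3-fold), the acute-phase protein ORM1 (26.7-fold), the long noncoding RNA LUCAT1 (24.6-fold), the complement receptor C5AR1 (22.2-fold), the collagen hydroxylase P3H2 (21.4-fold), the surface glycoprotein CD101 (19.4-fold), the phosphatase inhibitor PPP1R17 (18.0-fold) and the calcium-binding S100P (16.4-fold). Their standard errors ran from 0.11 to 0.23 on the log2 scale, and ORM1 has a close copy, ORM2, whose transcripts its probes may read. The largest decreases included BTLA, an inhibitory immune receptor (19.0-fold lower), the uncharacterised LOC105375878 (13.2-fold), the death ligand TNFSF10 (8.42-fold), the receptor P2RY8 (7.78-fold) and ELANE, neutrophil elastase (7.58-fold). MTARC2, ZBTB16, RXFP1 and PLPPR3 were 6.89-fold, 6.60-fold, 6.21-fold and 5.80-fold lower.

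Within the ATF4 list (29 of 29 members higher, 29 adjusted over the list alone, camera adjusted p = 6.67e-38) the largest changes were in DDIT4, SLC7A11 (14.5-fold higher, log2 3.86 ± 0.09), CHAC1, which cleaves glutathione (12.7-fold), and the mitochondrial folate enzyme ALDH1L2 (10.1-fold). The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 11 members of 19 and fell in 3 (12 and 4 adjusted over the list alone, camera adjusted p = 2.11e-05). WARS1 was 6.87-fold, CARS1 3.81-fold, SARS1 2.91-fold and MARS1 2.71-fold higher. NRF2 targets rose in 15 of 25 members and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 5.36e-13), with NQO1 6.34-fold higher, OSGIN1 5.37-fold and the sulfiredoxin SRXN1 4.68-fold. HMOX1 was 1.39-fold higher (adjusted p = 0.00517). All 3 of these lists stayed called with an estimated correlation (adjusted p = 0.000543, 0.0467 and 0.00713).

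In the NF-kB and inflammatory cytokine list 18 of 27 members were higher and 1 lower with AZA (19 and 1 adjusted over the list alone, camera adjusted p = 1.87e-10), led by IL1B (10.4-fold), the neutrophil chemokine CXCL8 (9.36-fold), TNF (5.16-fold) and TRAF1 (4.87-fold). Immediate early genes rose in 12 of 23 and fell in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 1.22e-06), with DUSP1 3.67-fold, KLF6 3.57-fold and ATF3 3.48-fold higher, and JUN, a subunit of AP-1, higher too (adjusted p = 9.86e-09). Autophagy and lysosome genes rose in 14 of 27 and fell in 1 (14 and 2 adjusted over the list alone, camera adjusted p = 6.92e-07), with the autophagy receptor SQSTM1 3.64-fold, GABARAPL1 2.80-fold, TFE3 2.62-fold and NBR1 1.95-fold higher. These 3 lists held with an estimated correlation, at adjusted p = 0.00381, 0.0411 and 0.0391.

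Apoptosis genes moved both ways with AZA. The BCL2 family and caspase list had 10 of 27 members higher and 4 lower (11 and 6 adjusted over the list alone, camera adjusted p = 0.00981, and adjusted p = 0.0434 with an estimated correlation). The proapoptotic BMF (5.59-fold) and PMAIP1 (4.38-fold) and the antiapoptotic BCL2A1 (3.62-fold) were higher, and the antiapoptotic BCL2 was 2.82-fold lower. The p53 targets had 12 of 31 higher and 4 lower (12 and 5 adjusted over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.0434 with an estimated correlation). SESN2, a stress-induced inhibitor of mTORC1 that is also on the ATF4 list, was 6.99-fold higher, TP53INP1 5.35-fold and the death receptor TNFRSF10B 2.77-fold. CDKN1A was 2.06-fold higher (adjusted p = 4.62e-06) and BBC3 1.47-fold higher (adjusted p = 0.00302), while MDM2 stood at -0.09 ± 0.10 (log2, SE, adjusted p = 0.656).

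MYC targets and ribosome biogenesis fell with AZA in 28 of 29 members (28 adjusted over the list alone, camera adjusted p = 2.78e-22, and adjusted p = 0.00568 with an estimated correlation), with UTP20 2.93-fold, MYC itself 2.40-fold, the spermidine synthase SRM 2.31-fold and RRS1 2.29-fold lower. Cholesterol synthesis and uptake fell in 16 of 18 (17 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.32e-13, and adjusted p = 0.000633 with an estimated correlation), with DHCR7 3.42-fold, MSMO1 2.40-fold, EBP 2.16-fold and HMGCS1 2.11-fold lower. Oxidative phosphorylation fell in 15 of 25 (20 adjusted over the list alone, camera adjusted p = 2.95e-09, but adjusted p = 0.16 with an estimated correlation), with the respiratory chain subunits UQCRQ 1.93-fold, NDUFS3 1.86-fold, NDUFV1 1.63-fold and NDUFA9 1.61-fold lower. Proteasome subunits fell in 10 of 26 (13 adjusted over the list alone, camera adjusted p = 1.12e-05, but adjusted p = 0.16 with an estimated correlation), with PSMB3 1.43-fold, PSMB6 1.39-fold, PSMD11 1.35-fold and PSMD1 1.34-fold lower. PSMB6 lost its call without AZA replicate 1 (adjusted p = 0.095), NT replicate 1 (0.0866) or NT replicate 2 (0.0688), without moderation (0.0589) and with the compared groups alone (0.0532), and its range over the alternatives was 0.00929 to 0.095. Heat shock genes fell in 11 of 26 and rose in 3 (11 and 4 adjusted over the list alone, camera adjusted p = 0.00094, and adjusted p = 0.0198 with an estimated correlation). HSPA4L was 2.28-fold, FKBP4 1.78-fold and HSPB1 1.66-fold lower, and DNAJB4 was 1.77-fold higher.

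Stem and progenitor genes fell in 10 of 23 members with AZA (10 adjusted over the list alone, camera adjusted p = 1.07e-06, and adjusted p = 0.00734 with an estimated correlation). Beside MYB and ELANE, the granule protease PRTN3 was 5.75-fold and the myeloid repressor GFI1 4.73-fold lower. In the FLT3 and leukaemia kinase signalling list 16 of 33 members were higher and 6 lower (16 and 6 adjusted over the list alone, camera adjusted p = 0.00782, but adjusted p = 0.162 with an estimated correlation). The receptors FLT3 and KIT were 2.62-fold and 3.21-fold lower, against the list's direction, while the ERK phosphatase DUSP5 was 6.19-fold and the cytokine receptor CSF2RA 2.44-fold higher. Monocytic and granulocytic maturation genes were not called as a list (adjusted p = 0.17), with 9 of 26 higher and 5 lower by either count. ITGAX, the CD11c integrin, was 14.4-fold and MPEG1 2.22-fold higher, and VCAN was 1.89-fold and IRF8 1.72-fold lower.

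G1/S and replication genes fell with AZA in 14 of 31 and rose in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00516, but adjusted p = 0.321 with an estimated correlation), with the uracil glycosylase UNG 2.05-fold, GINS2 1.70-fold and GINS1 1.69-fold lower and cyclin CCNE2 1.88-fold higher. G2/M genes were not called (adjusted p = 0.249), with 3 of 34 higher and 6 lower (3 and 7 adjusted over the list alone), MAD2L1 being 1.69-fold and CCNB1 1.32-fold lower and the phosphatases CDC25C 1.59-fold and CDC25B 1.41-fold higher. Nucleoside and azacitidine metabolism fell in 8 of 25 and rose in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0265, but adjusted p = 0.167 with an estimated correlation). In it the pyrimidine synthesis enzymes DHODH and CAD were 2.52-fold and 1.64-fold, NME1 2.33-fold and the nucleoside transporter SLC29A1 1.77-fold lower, and the list's call was lost without NT replicate 1 (adjusted p = 0.0623) and with dim genes left out (0.0567). DNA damage response and repair genes fell in 9 of 24 (9 adjusted over the list alone, camera adjusted p = 0.0265, but adjusted p = 0.324 with an estimated correlation), with the helicase WRN 1.56-fold, the kinase ATR 1.48-fold, PARP1 1.43-fold and FANCB 1.40-fold lower. FANCB lost its call without AZA replicate 3 (adjusted p = 0.059), NT replicate 2 (0.0551) or NT replicate 3 (0.0568), and its range was 0.00605 to 0.059. The list's call was lost without NT replicate 3 (adjusted p = 0.0772), without AZA replicate 3 (0.0521) and with dim genes left out (0.0567).

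Replication-dependent histones rose in 13 of 24 members with AZA and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.000192, but adjusted p = 0.167 with an estimated correlation), with H3C1 3.52-fold, H2BC9 2.64-fold, H4C1 2.28-fold and H4C2 1.91-fold higher, though probes of these similar genes may read each other's transcripts. Interferon-stimulated genes rose in 11 of 34 and fell in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 0.00279, but adjusted p = 0.121 with an estimated correlation). IFI6 was 2.10-fold and IFIT5 1.75-fold higher, IRF7 was higher too (adjusted p = 1.03e-06), and CMPK2 was 2.24-fold lower. The DNA methylation machinery was not called (adjusted p = 0.679; median -0.03, mean 0.04), with 3 of 16 higher and 1 lower by either count. The methyl-CpG binding protein ZBTB38 was 1.79-fold, the demethylating enzyme TET2 1.41-fold and the methyltransferase DNMT3A 1.31-fold higher, and DNMT3B was 1.26-fold lower (adjusted p = 0.0464). The call of DNMT3B was lost without any 1 of the AZA arrays (0.0874, 0.0687 and 0.151 for replicates 1 to 3), without NT replicate 2 (0.0671) or 3 (0.181), and under median centring (0.0583), array weights (0.0728), no moderation (0.0812) and the compared groups alone (0.0534). DNMT1 stood at -0.17 ± 0.07 (log2, SE, adjusted p = 0.11), and it was called with a trended and robust variance (0.0272) and without moderation (0.00855), over a range of 0.00855 to 0.281.

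Of 28 cancer-testis and germline genes, a class often silenced by DNA methylation, 1 was higher and 0 adjusted over the list alone, and the list was not called (adjusted p = 0.403). That 1 gene, MAGEA4, was 1.28-fold higher (adjusted p = 0.0424), a call lost under a repeated quantile normalization (0.0627), median centring (0.0581), a trended and robust variance (0.0547), no moderation (0.0826) and the compared groups alone (0.117). It was also lost without NT replicate 1 (0.158), NT replicate 3 (0.142), AZA replicate 2 (0.173) or AZA replicate 3 (0.0755), over a range of 0.00498 to 0.173. MAGEA1 stood at 0.38 ± 0.19 (log2, SE, adjusted p = 0.211) and, of its alternatives, was called only when AZA replicate 1 was left out (0.0432).

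**Figure D3:**
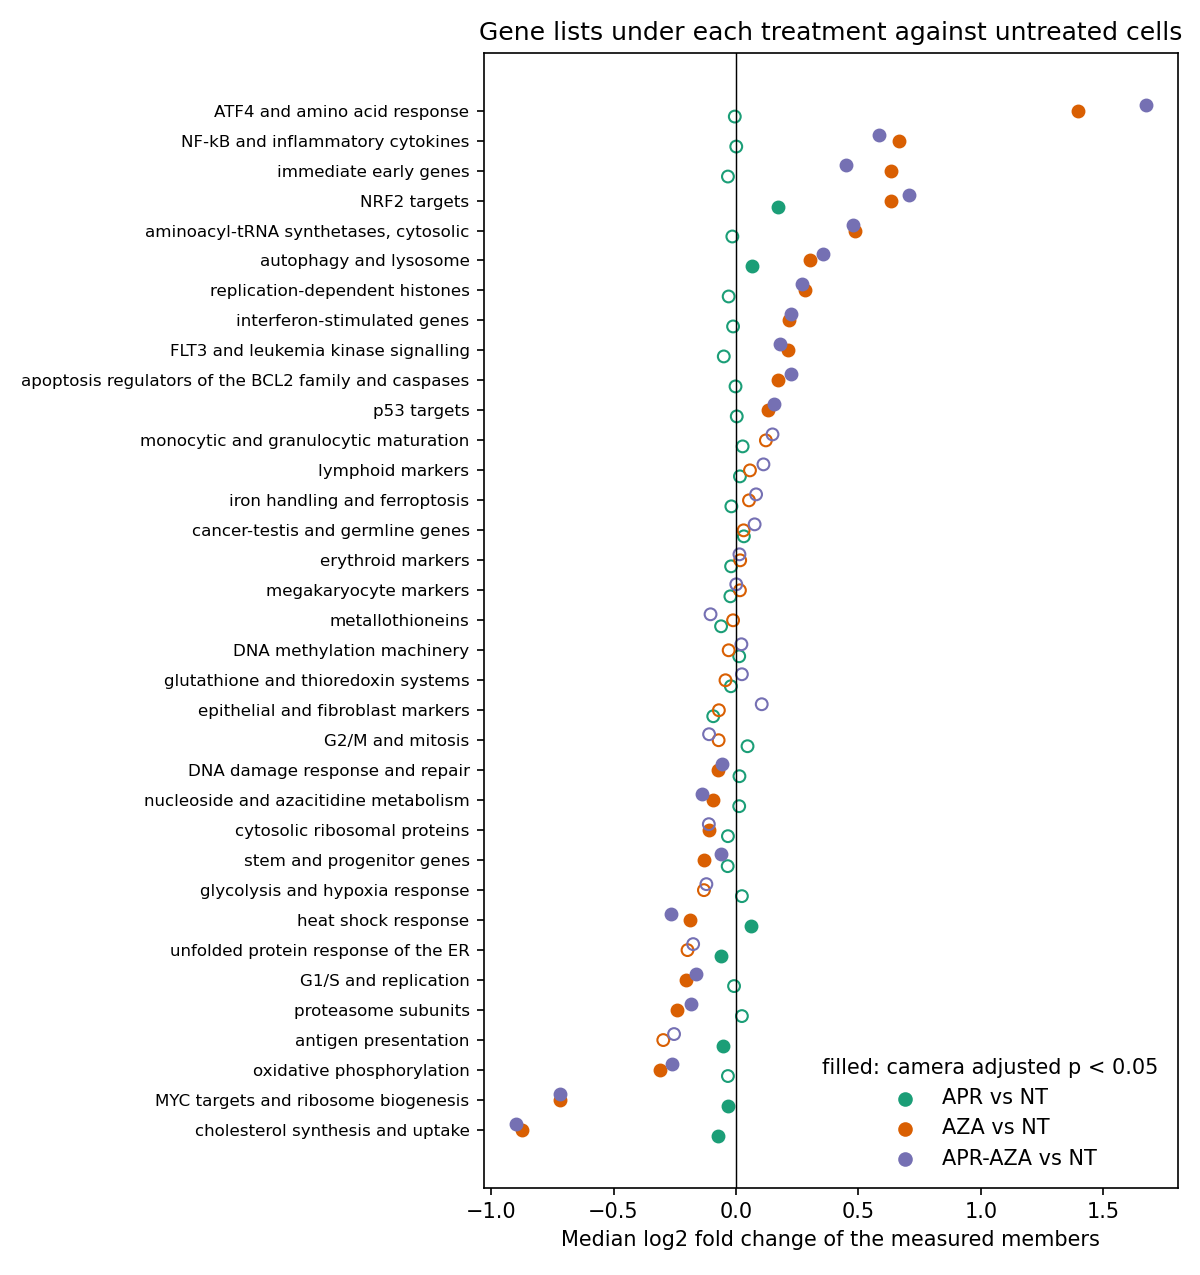
Each row is a gene list and each point the median log2 fold change of its measured members (horizontal axis) for APR, AZA or APR-AZA against NT, filled where camera's adjusted p was under 0.05 at the preset correlation. The ATF4 list has the highest median with AZA, 1.40, and cholesterol synthesis and uptake the lowest, -0.88, while APR medians lie close to 0.

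The combination was then compared with untreated cells. CLDN1 was 79.7-fold higher, DDIT4 32.2-fold and SLC7A11 15.3-fold, and BTLA was 19.4-fold and MYB 10.2-fold lower (standard errors 0.09 to 0.20 on the log2 scale, n = 3 per group). Genes of the ATF4 list rose in 29 of 29 members, by a median of 1.67 (29 adjusted over the list alone), with CHAC1 13.3-fold and ALDH1L2 9.87-fold higher. MYC targets and ribosome biogenesis fell in 28 of 29 (28 adjusted over the list alone), by a median of -0.72, with UTP20 3.05-fold, NOC3L 2.61-fold and RRS1 2.49-fold lower. NRF2 targets rose in 17 of 25 members and fell in 0 (17 adjusted over the list alone), by a median of 0.71, with NQO1 6.31-fold, OSGIN1 6.20-fold and SRXN1 5.78-fold higher. With limma, 6279 genes were called, 2924 higher and 3355 lower, with 530 at least 2-fold higher and 480 at least 2-fold lower.

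Among the 10 largest increases of the combination, LUCAT1 was 29.3-fold, ORM1 28.5-fold, BET1-AS1 25.1-fold, C5AR1 22.9-fold, CD101 19.9-fold, PPP1R17 18.9-fold, S100P 18.5-fold and P3H2 17.9-fold higher. Among the 10 largest decreases, LOC105375878 was 14.3-fold, TNFSF10 8.77-fold, P2RY8 8.64-fold, RXFP1 8.25-fold, ELANE 7.21-fold, the GABA receptor subunit GABRA4 6.90-fold, MTARC2 6.83-fold and the chemokine receptor CCR2 6.67-fold lower. PMAIP1 was 4.54-fold, CDKN1A 2.41-fold, BBC3 1.56-fold and HMOX1 1.41-fold higher, and FLT3 was 2.67-fold and MYC 2.56-fold lower, all called (adjusted p of 0.00393 or less). MDM2 (-0.17 ± 0.10, adjusted p = 0.288) and DNMT1 (-0.17 ± 0.07, adjusted p = 0.0997) were not, and DNMT1 was called with a trended and robust variance (0.0242) and without moderation (0.00761), over a range of 0.00761 to 0.273.

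Of the 35 lists, 20 were called with the combination, 10 of them also with an estimated correlation, and fry called 32. Those called both ways were the ATF4 list, MYC targets, NRF2 targets, cholesterol synthesis, NF-kB, autophagy, immediate early genes, stem and progenitor genes, heat shock and p53 targets, with adjusted p from 0.000612 to 0.0492 with an estimated correlation. The NF-kB list had 19 of 27 members higher and 2 lower by either count, with IL1B 9.74-fold, CXCL8 9.13-fold and TRAF1 5.31-fold higher and the TNF-induced TNFAIP2 up by 2.23 on the log2 scale. The p53 targets had 12 of 31 higher and 6 lower (14 and 6 adjusted over the list alone), with SESN2 7.73-fold, TP53INP1 5.95-fold and TNFRSF10B 2.92-fold higher. The aminoacyl-tRNA synthetases had 11 of 19 higher and 3 lower (12 and 3 adjusted over the list alone), with WARS1 7.41-fold, CARS1 3.93-fold, SARS1 3.03-fold and MARS1 2.93-fold higher, and adjusted p = 0.0518 with an estimated correlation.

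Cancer-testis and germline genes were not called as a list with the combination either (camera adjusted p = 0.324, and adjusted p = 0.379 with an estimated correlation), while fry called them (0.036), and 2 of 28 members were higher by either count. MAGEA4 was 1.43-fold higher (adjusted p = 0.00478) and stayed called under all its alternatives (0.000684 to 0.0242). MAGEA1 was 1.62-fold higher (adjusted p = 0.0167), a call lost without APR-AZA replicate 2 (0.0523), APR-AZA replicate 3 (0.0631), NT replicate 2 (0.0687) or NT replicate 3 (0.0642) and without moderation (0.0657), over a range of 0.00493 to 0.0687. Neither gene was called for APR-AZA against AZA (adjusted p = 0.986 for both), a comparison for which they were chosen after their values were seen. DNMT3B was 1.34-fold lower with the combination (adjusted p = 0.013), a call lost without APR-AZA replicate 2 (0.0668) or NT replicate 3 (0.0629), over a range of 0.00362 to 0.0668.

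What APR added to AZA was tested directly. SRXN1 had a log2 value of 0.31 ± 0.08 (SE, n = 3 per group) and the epoxide hydrolase EPHX1 one of 0.35 ± 0.08, and the steroid reductase AKR1C3 stood at 0.36 ± 0.13, and none of these was called (adjusted p = 0.986 for EPHX1 and AKR1C3). NQO1, at 10.55 ± 0.11 (log2, SD) in AZA and 10.55 ± 0.06 in APR-AZA, stood at -0.01 ± 0.09, and SRXN1 and NQO1 were chosen for this comparison after their values were seen. With limma, 0 of 28125 genes were called, against 1319 at an unadjusted p under 0.05 where 1406 would be reached by chance, and the 95% interval excluded a 2-fold change either way for 99.5% of genes. NRF2 targets had a median of 0.07 and were called by camera (adjusted p = 0.000217), but adjusted p = 0.287 with an estimated correlation. In that list 0 of 25 members were called over all genes and 2 adjusted over the list alone. Epithelial and fibroblast markers, a check on other cell types, had a median of 0.11 (camera adjusted p = 0.0204, but adjusted p = 0.287 with an estimated correlation), with 0 of 16 members called by either count and the keratins KRT19 and KRT7 at 0.63 ± 0.22 and 0.27 ± 0.17. That call was lost without APR-AZA replicate 1 (adjusted p = 0.193), AZA replicate 1 (0.0751) or AZA replicate 2 (0.091).

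Departure from additivity was tested as the change with both drugs minus the sum of the separate changes on the log2 scale. With limma, 0 genes were called, against 990 at an unadjusted p under 0.05, and the smallest adjusted p was 0.399. Camera called 3 lists and fry called 0. Epithelial and fibroblast markers had a median of 0.15 (adjusted p = 0.0102, but adjusted p = 0.112 with an estimated correlation), with KRT19 at 0.85 ± 0.32 and KRT7 at 0.65 ± 0.23 (SE). Heat shock genes had a median of -0.11 (adjusted p = 0.0102, but adjusted p = 0.112 with an estimated correlation), with HSPA1B at -0.30 ± 0.13 and HSPA1A at -0.26 ± 0.15. Antigen presentation had a median of 0.09 (adjusted p = 0.041, but adjusted p = 0.738 with an estimated correlation), with HLA-DPB1 at 0.36 ± 0.14 and the immunoproteasome subunit PSMB9 at 0.33 ± 0.17, and 0 members of any of the 3 lists were called by either count. The epithelial call was lost without APR replicate 3 (adjusted p = 0.0604), and the heat shock call without APR replicate 2 (0.0639). The antigen presentation call was lost without APR replicate 1 (0.49), APR-AZA replicate 1 (0.125), APR-AZA replicate 2 (0.103), AZA replicate 1 (0.379) or NT replicate 1 (0.472). The number of lists called rose to 6 without NT replicate 3 and to 5 without AZA replicate 2 or AZA replicate 3.

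What AZA added to APR was tested next, and its 5 largest changes each way were in genes also among the 10 largest with AZA alone. CLDN1 was 71.0-fold, DDIT4 35.2-fold, ORM1 33.0-fold, BET1-AS1 21.2-fold and CD101 19.2-fold higher in APR-AZA than in APR (standard errors 0.11 to 0.20 on the log2 scale, n = 3 per group). BTLA was 13.9-fold, LOC105375878 11.8-fold, MYB 8.86-fold, P2RY8 7.41-fold and TNFSF10 7.38-fold lower. With limma, 5813 genes were called, 2659 higher and 3154 lower. Genes of the ATF4 list rose in 29 of 29 members (29 adjusted over the list alone), with CHAC1 13.8-fold, SLC7A11 12.3-fold and ALDH1L2 8.91-fold higher. MYC targets fell in 27 of 29 (28 adjusted over the list alone), with UTP20 at -1.59 on the log2 scale and POLR1B 2.38-fold, NOC3L 2.36-fold and RRS1 2.33-fold lower. Heat shock genes fell in 15 of 26 and rose in 4 (17 and 4 adjusted over the list alone), with HSPA4L 2.61-fold, HSPA1A 1.90-fold, HSPA1B 1.87-fold and FKBP4 1.83-fold lower. These lists held with an estimated correlation (adjusted p = 0.000475, 0.00565 and 0.00565), as 10 of the 21 lists called did.

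The single drugs were also compared with each other. MYB was 7.56-fold, BTLA 13.6-fold, LOC105375878 10.9-fold, TNFSF10 7.09-fold and ELANE 6.80-fold higher with APR than with AZA (n = 3 per group). CLDN1 was 65.3-fold, ORM1 30.9-fold, DDIT4 30.3-fold, BET1-AS1 24.0-fold and CD101 18.7-fold lower. Limma called 5535 genes, 2972 higher with APR and 2563 lower. The ATF4 list was lower with APR in 29 of 29 members (29 adjusted over the list alone), with CHAC1 13.1-fold, SLC7A11 11.7-fold and ALDH1L2 9.11-fold lower. NRF2 targets were lower in 15 of 25 and higher in 1 by either count, with SRXN1 3.78-fold, OSGIN1 3.65-fold and NQO1 3.38-fold lower. Both lists were called with an estimated correlation too (adjusted p = 0.000424 and 0.00933).

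The changes with AZA and with APR-AZA overlapped in 2370 genes higher in both and 2782 lower in both, with 0 in opposite directions, where independent lists of these lengths would share 286 and 373. Across genes, which are not independent replicates, their log2 fold changes correlated at 0.95, against 0.50 in simulated unchanged groups with the same controls, and the covariance was 0.163 against 0.0077. The changes with APR and AZA correlated at 0.317 against the simulated 0.50, with a covariance of 0.016 against 0.0077. Those of APR and APR-AZA correlated at 0.325 against 0.50, with a covariance of 0.0171 against 0.0077. The correlations with APR thus lay below the simulated value, while the covariances lay above it. The simulation took all groups as unchanged. The log2 fold changes had an SD of 0.125 with APR, but 0.406 with AZA and 0.423 with APR-AZA. A wider spread lowers the correlation that shared arrays give, but not the covariance, so 0.50 is too high a reference for APR. NQO1, the 1 gene called with APR, was higher in all 3 comparisons with NT. The comparisons share the 3 NT arrays, which are too few to be split between them.

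**Figure D4:**
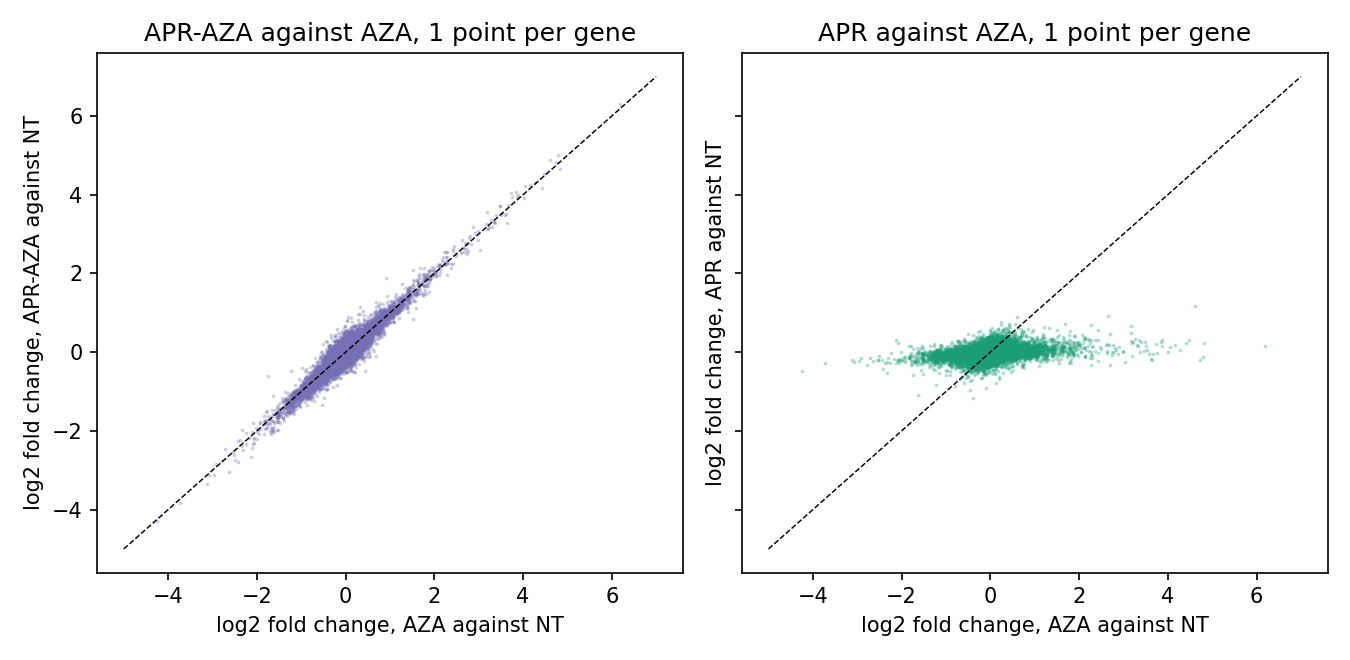
Each point is 1 gene, with the log2 fold change of AZA against NT on the horizontal axis and that of APR-AZA (left) or APR (right) against NT on the vertical axis; the dashed line marks equal change. The left cloud follows the line (correlation 0.95), and the right cloud is nearly flat, with no APR value beyond 1.18 either way.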

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

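The tests of carry-over, of scaling, of a distortion that depends on signal and of the width of the intervals below were chosen only after the results they bear on were seen.

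Rows without a gene symbol, which the comparisons did not use, were called at shares close to those of the named genes. Of 1284 such rows, 237 were called with AZA against NT (110 higher and 127 lower) and 261 with APR-AZA against NT (132 higher and 129 lower). Of the named genes, 20.9% and 22.33% were called in these comparisons.

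Differences between the effect of APR with and without AZA were seen in 3 lists by camera at its preset correlation. The adjusted p was 0.0102 for epithelial and fibroblast markers, 0.0102 for heat shock genes and 0.041 for antigen presentation. With an estimated correlation the adjusted p was 0.112, 0.112 and 0.738, and fry called 0 of the 35 lists. When APR labels were exchanged among the 6 arrays without AZA and among the 6 with it, 23 of 100 splits, the real one included, called at least the 3 lists of the real split, and the highest of the others called 11, so chance is not excluded. For single genes the splits test nothing, since a real count of 0 is reached by all 100 of them whatever the data; the highest of the others called 1 gene.

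The pattern weighed first is the rise of NQO1 and the NRF2 targets with APR alone. If AZA-treated RNA had been carried over into the APR arrays, genes that AZA raised most should imply the same share of it as NQO1, which implies 16.4% (95% interval 11.7 to 21.7%). The 10 genes that AZA raised most imply a median of 0.646%, and at most 5.38% (LUCAT1), and all 502 genes that AZA raised at least 2-fold imply a median of 2.52% (quartiles -0.433 to 7.28%), although 60 of them reach 11.7%, so carry-over does not account for the rise of NQO1 as a whole. A constant per array cancels by construction when the list is set against all genes, where its mean rose by 0.197 (log2, SE 0.040). Camera had already called the list against other genes on these arrays, so that value restates the call and is no separate evidence. Against the 100 genes nearest in mean signal to each member the mean rose by 0.192 (SE 0.031). A distortion that depends on signal therefore does not account for the list's rise, and a response to APR stays open. The 10 splits of 6 arrays are too few for a share under 0.05: the real one called 1 gene and 7 lists, the highest of the others 1 gene and 9 lists, and 2 of the 10 splits reached each real value.

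The pattern weighed second is that no gene was called by limma for APR on top of AZA (1319 at an unadjusted p under 0.05). Too few arrays could hide small changes, but the 95% interval excludes a 2-fold change for 99.5% of genes, so lack of precision does not account for missing 2-fold changes in the measured signal. No filter on signal was applied and fold changes of dim genes are understated, so true 2-fold changes of such genes are not excluded. The tables argue against a signal ceiling as well: in AZA cells 1 of the 25 NRF2 targets, FTL at 12.88 (chosen after its values were seen), lay within 1 log2 unit of the array's upper end of 13.70, and NQO1 stood at 10.55. Changes under 2-fold, and a biological limit on further NRF2 target expression in AZA cells, stay open and untested.

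The pattern weighed last is that fold changes of APR alone ran with those of AZA across genes (r = 0.317), a value that shared untreated arrays can raise. Simulated unchanged groups that shared these arrays had a mean covariance of 0.0077, where 0.016 was observed. Against the AZA change averaged over both APR states, the correlation was 0.18. That change is measured from the mean of the NT and APR arrays together, so shared arrays give no correlation on average. The highest of the 9 other splits of the 6 arrays without AZA gave 0.124, with an SD of 0.076 between them, so 0.18 lies above them by less than that SD. Shared untreated arrays thus do not give the 0.18 on average. Chance differences between arrays and a weak common response cannot be told apart here, because the splits are few and the gap is small.

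For the other comparisons 10 splits of 6 arrays are too few to give a share under 0.05. With AZA against NT the real split called 5878 genes and 21 lists, and the highest of the others 0 genes and 14 lists; in both counts 1 of the 10 splits, the real one, reached the real value. The same count of 1 of 10 splits held for APR-AZA against NT (6279 genes and 20 lists; highest others 0 and 12), APR-AZA against APR (5813 and 21; 0 and 12) and APR against AZA (5535 and 22; 0 and 15). With APR-AZA against AZA the real count of 0 genes is reached by all 10 splits whatever the data (0 in the highest of the others), and 3 of 10 splits gave its 2 lists or more, with 3 lists in the highest of the others. Splits that called 0 genes still called up to 15 lists at camera's preset correlation. In the comparisons that differ by AZA, each other split mixed arrays with and without AZA unequally. Part of the AZA change thus stayed between its groups and the rest widened the spread, so these counts do not measure false calls.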

How the results depend on the processing

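The average of the APR effect over both AZA states was chosen after seeing the data; the other alternatives were planned. Of 8998 values of named genes under the alternatives, 8875 stayed on the same side of the threshold, 113 lost their call, 10 gained one and 0 called values turned direction; 13 of 1559 values that were not called changed sign. Of 1074 list results, 953 kept their call, 121 lost it and 0 turned. Most named genes were picked for large called changes in these data, which favours stable calls. Only lists already called were followed, so a gained list call could not be counted. These tallies thus do not measure how stable genes and lists are in general. For APR against NT the 1 gene called became 2 with dim genes left out, and 0 without moderation, with the compared groups alone, with at least a 2-fold change, at an adjusted p under 0.01 and for the APR effect averaged over both AZA states (limma; 1382 at an unadjusted p under 0.05). Requiring a 2-fold change left 908 genes for AZA against NT, 1010 for APR-AZA against NT, 853 for APR-AZA against APR and 752 for APR against AZA, which the threshold's own construction explains. Under the scalings, the median log2 fold change of all genes lay between -0.034 and 0.021 in every comparison.

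With an estimated correlation the lists called went from 7 to 2 for APR against NT, 21 to 12 for AZA against NT, 20 to 10 for APR-AZA against NT, 21 to 10 for APR-AZA against APR, 2 to 0 for APR-AZA against AZA, 3 to 0 for non-additivity and 22 to 11 for APR against AZA. Fry called 2, 27, 32, 27, 0, 0 and 25 in the same order, above camera's preset count in the 4 comparisons that differ by AZA and below it in the other 3. A repeated quantile normalization gave 5 for APR-AZA against AZA, and the cause was not tested.

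Leaving out each array in turn gave 0 to 2 genes for APR against NT (2 without APR replicate 1, 0 without NT replicate 2 or 3), 5086 to 5409 for AZA against NT, 5317 to 5944 for APR-AZA against NT, 4921 to 5275 for APR-AZA against APR, 4747 to 4975 for APR against AZA and 0 to 0 for APR-AZA against AZA and non-additivity. Lists ranged over 3 to 7, 19 to 22, 19 to 21, 20 to 22 and 20 to 22 in the first 5 of these, 1 to 3 for APR-AZA against AZA (1 without APR-AZA replicate 1) and 2 to 6 for non-additivity.

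Replicate numbers did not pair the arrays. Deviations of 18 same-numbered pairs correlated at -0.253 to 0.142, over 0.1 in 3, and 0 of 12 arrays correlated best with its own number. Pairs with different numbers correlated at -0.189 to 0.28, the highest being APR replicate 2 with NT replicate 1. A component shared between groups that does not follow the numbers is thus not excluded. No fit modelled one. With the number as a replicate block, the 1 gene of APR against NT became 0, and the counts were 5445 for AZA, 5857 for APR-AZA against NT, 5436 for APR-AZA against APR, 5093 for APR against AZA and 0 for the other 2 comparisons. With AZA against NT the block ended the calls of DNMT3B (adjusted p = 0.0638) and RPS14 (0.0597). Lists called by camera went from 7 to 5 for APR against NT, without the ER list (adjusted p = 0.0644) and MYC targets (0.0646). For non-additivity they went from 3 to 2, without antigen presentation (0.0516).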

Other observations

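The permutation test below was chosen only after camera's calls of its list had been seen.

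Among antigen presentation genes, not called as a list (camera adjusted p = 0.0726), 4 of 21 were higher and 9 lower with AZA (6 and 9 adjusted over the list alone). The class II genes HLA-DMB, HLA-DRA and HLA-DQA1 were 2.03-fold, 2.02-fold and 1.93-fold lower and the class I gene HLA-E 1.71-fold higher. Iron handling and ferroptosis genes also split, 9 of 20 higher and 7 lower by either count (adjusted p = 0.189), with SLC7A11 14.5-fold and CHAC1 12.7-fold higher and the ferrireductase STEAP3 3.58-fold and the iron exporter SLC40A1 2.85-fold lower. The metallothionein list was not called (adjusted p = 0.68), with 1 of 11 higher and 2 lower by either count, MT2A being 2.38-fold higher and MT1X 2.03-fold and the zinc exporter SLC30A1 1.24-fold lower, though probes of these similar genes may read each other's transcripts. SLC30A1 lost its call without AZA replicate 1 (0.055) or NT replicate 2 (0.0658), over a range of 0.00583 to 0.0658. Of 12 megakaryocyte markers 1 was called, the matrix protein THBS1, 16.1-fold higher. The megakaryocyte, erythroid, lymphoid and epithelial lists were not called with AZA (camera adjusted p = 0.351, 0.977, 0.403 and 0.891), with 1, 0, 1 and 1 members higher and 0 lower, among them NKG7 (1.68-fold) and FN1 (2.05-fold).

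In the unfolded protein response of the ER, EDEM1 was 2.53-fold and the sensor ERN1 2.36-fold higher with AZA, while SDF2L1 was 2.59-fold and DERL3 2.35-fold lower, and the list was not called (camera adjusted p = 0.249, 6 of 22 higher and 9 lower; 7 and 10 adjusted over the list alone). Glycolysis and hypoxia genes split likewise (adjusted p = 0.31, 6 of 28 higher and 10 lower; 6 and 11 adjusted over the list alone), with the growth factor VEGFA 3.17-fold and ADM 3.10-fold higher and the lactate dehydrogenase LDHA 1.75-fold and GPI 1.65-fold lower. Glutathione and thioredoxin genes had 6 of 30 higher and 10 lower by either count (adjusted p = 0.57), with the reductases TXNRD1 3.49-fold and GSR 2.13-fold higher and the peroxiredoxin PRDX4 2.12-fold and CHAC2 2.09-fold lower. Cytosolic ribosomal proteins were lower in 4 of 27 members (3 adjusted over the list alone). That share is close to the 2855 of 17812 protein-coding genes called lower with AZA. Camera called the list (adjusted p = 0.0229, but adjusted p = 0.418 with an estimated correlation). Its call was lost without NT replicate 1 (0.0919) or AZA replicate 1 (0.127) and with dim genes left out (0.0502). RPL7 was 2.26-fold, RPS14 1.44-fold, RPL6 1.33-fold and RPS15 1.27-fold lower. RPS14 lost its call without NT replicate 1 (0.153), NT replicate 2 (0.119), AZA replicate 1 (0.182) or AZA replicate 3 (0.148), without moderation (0.116), with array weights (0.077) and with the compared groups alone (0.111), and RPL6 without NT replicate 2 (0.0528), over ranges of 0.00165 to 0.182 and 0.00655 to 0.0528. By gene type, 29.1% of 17812 protein-coding genes were called with AZA, 20.8% of 313 small nucleolar RNAs and 5.92% of 7317 long noncoding RNAs. These shares were not adjusted for signal, and fold changes of dim genes are understated. They therefore do not show that AZA affects 1 type less than another.

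The mean log2 signal of the 25 measured targets was 7.61 ± 0.05 (SD, n = 3) in NT and 7.81 ± 0.04 in APR, and 8.56 ± 0.02 in AZA and 8.67 ± 0.01 in APR-AZA. All 3 APR arrays lay above all 3 NT arrays (7.76 to 7.85 against 7.56 to 7.65), and all 3 APR-AZA arrays above all 3 AZA arrays (8.66 to 8.67 against 8.54 to 8.57). The difference was 0.20 without AZA and 0.11 with it, and a two-sided exact permutation test within AZA states, over 400 arrangements, gave p = 0.005, the smallest it can give. That p restates camera's calls of the list on the same arrays and is no separate evidence, so whether APR raises these genes in both AZA states stays open. With AZA present, the call was lost with an estimated correlation (adjusted p = 0.287) and with fry (0.181), and epithelial and fibroblast markers differed by a mean of 0.13. NQO1, chosen for the comparison with AZA after its values were seen, differed by 0.91 without AZA and by -0.01 with AZA. Limma's test of non-additivity, which compares these 2 differences, called 0 genes (smallest adjusted p = 0.399). That count is adjusted over all genes tested, so it does not decide the question for NQO1 alone. NQO1 stood at 10.55 ± 0.11 (log2, SD, n = 3) in AZA and 10.55 ± 0.06 in APR-AZA. A rise as large as 0.91 was thus not seen in cells with AZA. NQO1 was picked for its change without AZA, which can overstate that change. Whether the NQO1 change was lost under AZA therefore stays open.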
